A study of Xenopus laevis with 10 samples.

How the data were processed

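RNA was measured by high-throughput sequencing in the intestinal tubes of Xenopus laevis tadpoles that had been fed or left unfed, at 10, 13 and 16 days post fertilization (dpf). Per the labels, the tadpoles were raised at 19 °C and 20 to 26 tubes were pooled for each stage. The 10 libraries came from 2 experiments. Experiment 1 gave 1 fed and 1 unfed library at 10 and at 13 dpf, and experiment 2 gave 1 of each at 10, 13 and 16 dpf. The labels do not say whether the libraries came from separate clutches, tanks or extractions, and they describe the collection for 10 and 16 dpf without naming 13 dpf. All p-values therefore measure the spread between these libraries and no more. For 2 libraries of experiment 1 the age in the title differs from the age in the stage field: the fed library titled 13 dpf has 10 dpf there, and the unfed library titled 10 dpf has 13 dpf. The title was used, because with the titles experiment 1 fills every combination of age and feeding. The headers of its count columns also give the ages of the titles. The age from the stage field was tried as an alternative. With it both fed libraries of experiment 1 are 10 dpf and both its unfed libraries 13 dpf. Feeding and age then cannot be told apart within that experiment, and its pairs would compare different ages. Only experiment 2 would then give an unfed library at 10 dpf and a fed library at 13 dpf.

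The authors aligned the reads with HISAT2 and counted them with featureCounts, per the labels; the versions and the genome build are not given in the sources used here. The deposited tables hold raw counts in 10 columns, which the authors did not normalize. Each of the 63876 rows of a table is a transcript with its length in bases, a quantity other than counts that is given per the file headers. The 10 deposited columns of values scaled by length and depth (RPKM) were not used here. The variants of a gene hold nearly the same counts: of 9858 genes with at least 2 variants and 100 counts, 82.7% had their 2 highest variants within 10 percent of each other, so a read was counted for every transcript that it overlapped. Gene rows had been assumed before the data were examined. Each gene was therefore represented by its transcript with the highest total count, and 2 alternatives chosen after seeing the data used all transcript rows or the sum over a gene's transcripts. The 61159 rows with a RefSeq transcript accession were assigned to genes through a RefSeq gene table of the assembly Xenopus_laevis_v10.1, which was used for names only. Of these, 43396 were matched without the accession's version and 10476 with it. This gave 33655 genes, of which 26905 were in the gene table, and the matched genes held 93.0% of the gene counts; the others kept the deposited name. Rows with a blank name held 0.074% of the counts and named rows without an accession held 0.136%, and both were left out. Xenopus laevis is an allotetraploid, and the suffixes .L and .S name the copies of a gene on the long and short chromosomes of a pair. In 5 pairs of neighbouring genes the counts differed by less than counting noise, and none of the genes named in the text is among them.

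The gene total per library ran from 6996760 to 9931361 counts (deposited totals 12664503 to 17967762), with 26470 to 27845 genes at 1 count or more. Intervals and floors given for single values are 95 percent intervals and a floor of 3 counts per library, and they cover counting error only. Analyses were run in R 4.3.3. Genes with low counts were removed with filterByExpr, libraries were scaled by the trimmed mean of M values (TMM, factors 0.862 to 1.094), and genes were tested with edgeR 4.0.16 by the quasi-likelihood F test with robust dispersion estimates. Adjusted p-values are Benjamini-Hochberg values over all genes tested, with a threshold of 0.05. A log2 fold change is fed minus unfed, or 13 minus 10 dpf, and is given with its standard error (SE). Counts scaled to library size (CPM) are given as mean ± SD with n = 5 libraries per feeding state unless a group is named. The all-ages comparison used additive terms for experiment, age and feeding. The comparisons at 10 dpf and 13 dpf, the change of the fed minus unfed difference between these ages, and the comparisons of 13 with 10 dpf within unfed and fed tadpoles came from 1 fit with the experiment and the 6 groups as terms. The experiment was a block in every model, since the labels divide the study into 2 experiments; the difference between experiments correlated across genes between groups (r 0.341 to 0.54 over 6 pairs of groups; genes are not independent replicates). A feeding by experiment term tested whether the feeding effect differed between experiments. At 16 dpf each feeding state had 1 library, so log2 ratios of CPM with a prior count of 2 were taken and no test was made. There, the median of each gene list was placed among 10000 random lists of the same size matched on expression.

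Before the data were examined, 35 gene lists (1279 symbols) were fixed for pathways, cell types of the gut and tissues that a dissected tube might carry. Each list with at least 5 tested genes was tested with camera from limma 3.58.1, two-sided, at a preset correlation between genes of 0.01, and p-values were adjusted over the lists. The same test with an estimated correlation and fry, which tests whether a list's genes move on balance in 1 direction without comparing them with other genes, stand beside it. The genes to name were also fixed by a rule then. In the all-ages comparison these were the 12 highest and 12 lowest log2 fold changes among named genes past the threshold with a mean of at least 5 CPM and the same sign in all 5 pairs of libraries of an experiment and age. At a single age they were the 8 highest and 8 lowest with the same sign in both experiments, and at 16 dpf the 6 highest and 6 lowest ratios at a mean of at least 10 CPM. For the change from 10 to 13 dpf up to 6 and 6 were allowed. From each list up to 4 members past the threshold with the smallest p were named, or up to 2 where none passed.

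The models were tested on simulated data with the same design, in which 200 of 23081 genes were changed. Of these, 67 were changed by 1.5-fold, 67 by 2-fold and 66 by 4-fold. The changed genes were drawn only from those with a mean of at least 5 CPM, so recovery among genes below that was not measured. The all-ages model recovered 7.5%, 77.6% and 98.5% of these, with 15 false calls among 137. The models for a single age recovered 11.9% (10 dpf) and 10.4% (13 dpf) at 2-fold and 84.8% and 92.4% at 4-fold, with 13 false calls each among 77 and 81. For the change between ages the recovery was 0% at 2-fold and 50% at 4-fold, with 14 false calls among 47. For 13 against 10 dpf in unfed tadpoles it was 7.5% at 2-fold and 84.8% at 4-fold, with 9 false calls among 70. In fed tadpoles it was 10.4% at 2-fold and 89.4% at 4-fold, with 13 among 79. For the difference between experiments it was 3% at 2-fold and 66.7% at 4-fold, with 11 false calls among 57. Every model other than the all-ages model recovered 0% at 1.5-fold. False calls lay above the nominal 5 percent in every model. In the comparisons of fed with unfed, far more genes were called in the data than the 200 changed here. Recovery and the share of false calls depend on that number. Of 35 simulated lists, 3 were changed by 1.5-fold, and camera with the preset and the estimated correlation and fry each recovered 3 and called 0 others. In this simulation each gene was drawn independently and the experiments did not differ. It therefore cannot show which correlation between genes holds in the data.

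Alternatives fixed before the data were examined were DESeq2 size factors in edgeR, no low-count filter, a stricter filter (mean of at least 1 CPM), the DESeq2 1.42.0 Wald test, limma-voom, summed .L and .S copies, leaving out the 50 most abundant genes, leaving out each library in turn, no replicate block, a block for each pair of libraries, the age from the stage field, each experiment alone, and 10 and 13 dpf alone. Alternatives chosen after seeing the data were library size alone as the scaling, both ways of using all transcripts, leaving out the 2 libraries with conflicting ages, and, for the lists outside the all-ages comparison, an estimated correlation, fry, the age from the stage field and leaving out each library. To check for a bias by transcript length, a loess trend (span 0.5) of each library's log2 deviations from the gene means on log10 length was entered as an offset, and the all-ages test and camera were run again.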

Results

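The data are raw counts from 10 RNA sequencing libraries of intestinal tubes, 5 from fed and 5 from unfed Xenopus laevis tadpoles. At 10 dpf and at 13 dpf each feeding state had 2 libraries, 1 from each experiment, and at 16 dpf it had 1, from experiment 2. In experiment 1 the gene totals were 8359692 counts (fed, 10 dpf), 7677056 (fed, 13 dpf), 9931361 (unfed, 10 dpf) and 8993076 (unfed, 13 dpf). In experiment 2 they were 9016570, 8667260 and 7250537 counts in fed tadpoles and 6996760, 8196864 and 9278804 counts in unfed tadpoles at 10, 13 and 16 dpf. The first principal component of log2 CPM held 53.3% of the variance and placed the fed libraries between -72.92 and -52.5 and the unfed libraries between 30.89 and 84.24. The second held 18.7% and parted the experiments. Correlations across genes between libraries were 0.905 to 0.977 within a feeding state and 0.844 to 0.935 between the states.

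**Figure D1:**
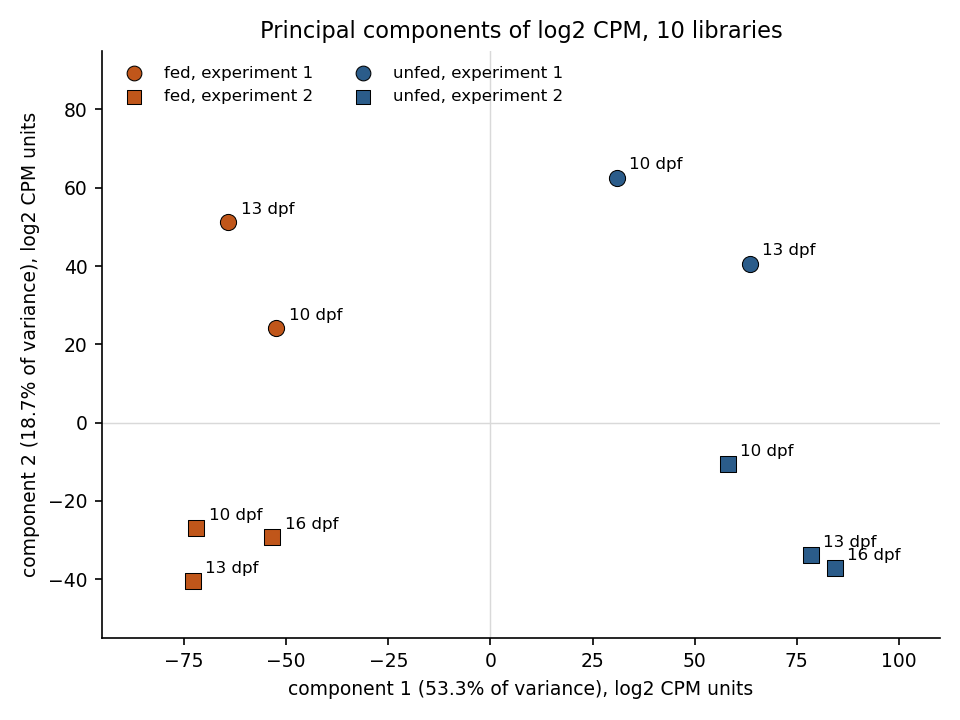
Principal components 1 and 2 of log2 CPM (axes in log2 CPM units, with the percent of variance) for the 10 libraries, coloured by feeding, shaped by experiment and labelled with age. Component 1 (53.3%) parts fed from unfed libraries and component 2 (18.7%) parts the experiments.

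The all-ages comparison asked how feeding changed the intestinal mRNA profile. Of the 12 highest genes that the rule names, 3 act on polyunsaturated fatty acids, 7 in sterol synthesis and 1 is a phosphate transporter gene. fads1.L, a fatty acid desaturase, rose by a log2 fold change of 7.20 ± 0.20 (SE; adjusted p 8.38e-09), from 0.393 ± 0.126 CPM in unfed to 61.7 ± 24.6 CPM in fed libraries (SD, n = 5 each, edgeR quasi-likelihood test). The phosphate transporter gene slc34a2.S rose by 6.44 ± 0.50 (adjusted p 4.17e-05) and the sterol synthesis genes msmo1.L and sqle.L by 5.94 ± 0.40 and 5.85 ± 0.28. Of the 12 lowest genes that the rule names over all genes, the first was cxcl8.S, which encodes a chemokine that attracts neutrophils, with a log2 fold change of -5.17 ± 0.76 (adjusted p 0.00154; 0.923 ± 0.846 CPM in fed and 47.1 ± 48.2 CPM in unfed libraries).

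Among the other genes with the highest fold changes were the desaturase gene fads2.S (6.19 ± 0.81, adjusted p 0.000982) and the elongase gene elovl2.L (5.14 ± 0.53), which act with fads1.L on polyunsaturated fatty acids. With them rose the sterol synthesis genes msmo1.S (5.76 ± 0.36), sqle.S (5.46 ± 0.32), cyp51a1.S (5.29 ± 0.40), hmgcs1.S (5.26 ± 0.35) and cyp51a1.L (5.10 ± 0.34). ppp1r3c.1.L, a subunit that directs a phosphatase to glycogen, rose by 4.99 ± 0.28. Among the lowest were noxo1.S, an organizer of an epithelial NADPH oxidase (-4.64 ± 0.43), arg1.L, an arginase (-4.37 ± 0.62), mmp8.L, a collagenase (-4.33 ± 0.99, adjusted p 0.0103), and acod1.L, the itaconate-forming enzyme of activated macrophages (-4.17 ± 0.66). crebrf.S, described as a CREB3 regulatory factor, had -4.10 ± 0.26 and the death ligand gene tnfsf10.L had -3.37 ± 0.14 (adjusted p 4.67e-07). The remaining genes of the lowest 12 were phyhdla.1.L (-3.67 ± 1.09, adjusted p 0.0283), clca1.2.L (-3.57 ± 0.79), the fatty acid amide hydrolase gene faah.1.S (-3.41 ± 0.24), foxr1.L, whose deposited description is a tetratricopeptide repeat protein (-3.34 ± 0.31), and ypel1.L (-3.30 ± 0.17). Each of these genes had the same sign in all 5 pairs, as the rule for naming required. Leaving out single libraries ended the call of mmp8.L (adjusted p 0.0543 without fed 16 dpf replicate 2 and 0.0552 without unfed 16 dpf replicate 2) and of phyhdla.1.L (adjusted p 0.0558 to 0.116 without any 1 of the 6 libraries of experiment 2).

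**Figure D2:**
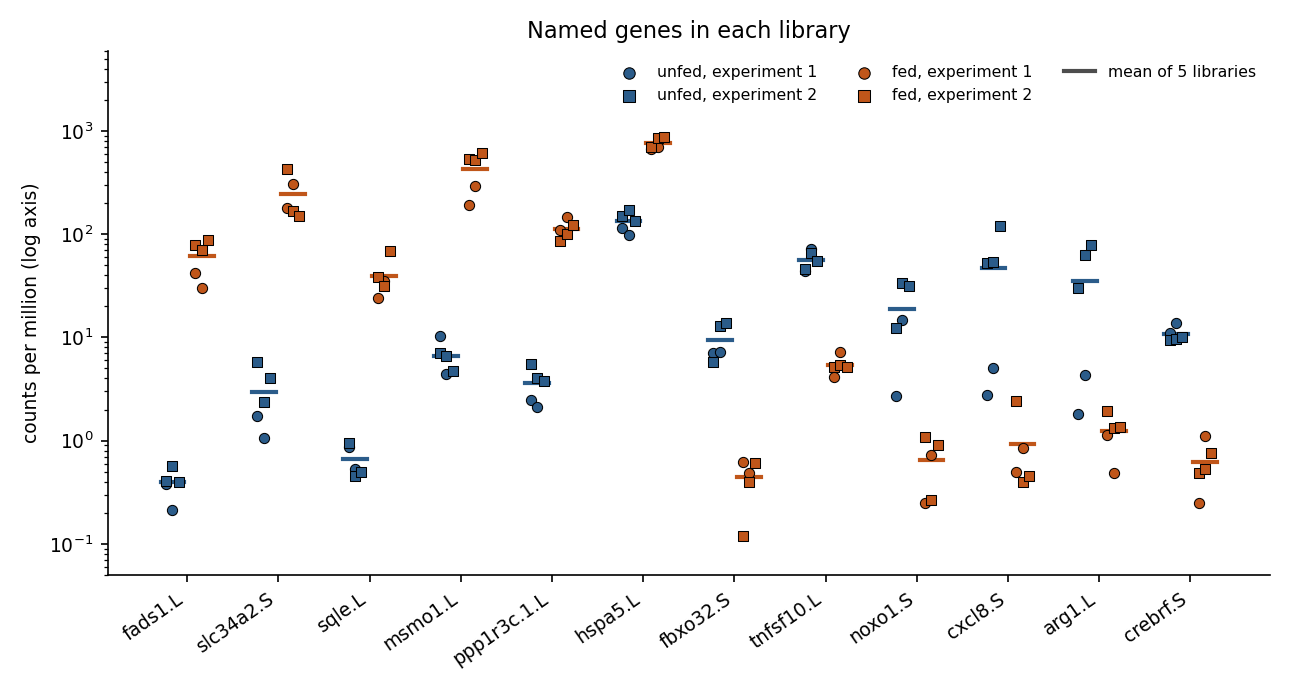
CPM (log axis) of 12 named genes in each of the 10 libraries, with the mean of the 5 fed and the 5 unfed libraries as bars; circles are experiment 1 and squares experiment 2. For fads1.L the means are 0.393 CPM in unfed and 61.7 CPM in fed libraries, and for cxcl8.S they are 47.1 and 0.923 CPM.

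Cholesterol synthesis was the list with the largest rise. Of its 44 genes, 40 rose and 1 fell (40 and 2 adjusted over the list alone), with a median log2 fold change of 2.72 (camera adjusted p 3.6e-46; adjusted p = 0.104 with an estimated correlation). fdps.L, nsdhl.L and fdft1.L rose by 3.55 ± 0.18, 2.99 ± 0.15 and 2.85 ± 0.15. Of 27 genes of fatty acid synthesis, 19 rose and 2 fell (19 and 2 adjusted over the list alone), with a median of 0.86 (camera adjusted p 8.52e-12; adjusted p = 0.0547 with an estimated correlation). The elongase genes elovl5.S and elovl5.L both rose by 3.22 ± 0.20, and aacs.L, which turns acetoacetate into a precursor of lipids, rose by 3.87 ± 0.29. Glycolysis had 21 of 38 genes higher and 3 lower (21 and 3 adjusted over the list alone). Its median was 0.65, and the camera adjusted p was 0.000352 (adjusted p = 0.104 with an estimated correlation). Among them were tpi1.L (1.39 ± 0.14), pkm.S (1.20 ± 0.13), pgam1.S (1.17 ± 0.13) and pgam1.L (1.74 ± 0.21).

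Of 89 genes of oxidative phosphorylation, 84 rose and 0 fell (84 and 0 adjusted over the list alone). Here the median was 0.80, with a camera adjusted p of 1.84e-16 (adjusted p = 0.389 with an estimated correlation). With a transcript length trend removed from each library it was 0.52. cycs.L, which encodes cytochrome c, rose by 1.62 ± 0.18, cyc1.L by 1.25 ± 0.13, the ATP synthase gene atp5f1b.L by 1.49 ± 0.18 and ndufs3.S by 1.17 ± 0.14. In the list of fatty acid oxidation and ketogenesis, 23 of 43 rose and 6 fell (28 and 6 adjusted over the list alone). For the list as a whole the median was 0.59 and the camera adjusted p 0.00455 (adjusted p = 0.578 with an estimated correlation). cpt2.S (1.36 ± 0.17) and etfa.S (1.14 ± 0.14), which act in the oxidation itself, rose, while pdk4.S and pdk4.L, kinases that hold back the entry of pyruvate into the citric acid cycle, fell by 2.54 and by 2.19 on the log2 scale. This list's call was lost without unfed 16 dpf replicate 2 (camera adjusted p 0.0502). Nutrient transporters had 19 of 41 genes higher and 5 lower (19 and 5 adjusted over the list alone). The list's median was 0.46, with a camera adjusted p of 0.00272 (adjusted p = 0.522 with an estimated correlation). slc34a2.L rose by 3.52 ± 0.34, and the amino acid transporter genes slc7a8.S and slc7a9.L by 1.89 ± 0.26 and 1.64 ± 0.25. Of 46 genes of xenobiotic metabolism, 22 rose and 7 fell (23 and 7 adjusted over the list alone). Its median was 0.54, and the camera adjusted p was 0.00732 (adjusted p = 0.129 with an estimated correlation). Among them were ugt1a1.L (1.83 ± 0.17), the xenobiotic receptor gene nr1i2.S (1.52 ± 0.17), gclc.L (1.11 ± 0.13) and cyp1a1.L (3.80 ± 0.50).

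Of 88 cell cycle genes, 73 rose and 0 fell (79 and 0 adjusted over the list alone). Here the median was 1.54, with a camera adjusted p of 4.39e-20 (adjusted p = 0.389 with an estimated correlation). Examples are the replication genes mcm2.L (2.70 ± 0.25), orc1.L (2.49 ± 0.26), mcm7.L (2.04 ± 0.21) and mcm7.S (1.97 ± 0.21). The list's counts made up 0.142% to 0.245% of the gene counts in fed libraries and 0.0669% to 0.0943% in 4 unfed libraries, and 0.153% in the unfed 10 dpf library of experiment 1. Ribosome biogenesis had 76 of 98 genes higher and 3 lower (78 and 3 adjusted over the list alone). For the list as a whole the median was 0.90 and the camera adjusted p 1.66e-12 (adjusted p = 0.522 with an estimated correlation). Examples are tsr1.L (1.76 ± 0.21), utp15.S (1.57 ± 0.16), wdr43.L (1.56 ± 0.16) and nip7.L (1.17 ± 0.14). Of 125 genes of cytosolic ribosomal proteins 0 passed over all genes by edgeR and 0 adjusted over the list alone (median -0.02, camera adjusted p 0.920). With a transcript length trend removed from each library this list passed lower in fed tadpoles (median -0.38, camera adjusted p 1.96e-05). rps9.L and rps9.S had -0.30 ± 0.19 and -0.33 ± 0.21, and rps9.L passed without fed 10 dpf replicate 1 (adjusted p 0.038). Chaperones and folding enzymes of the endoplasmic reticulum had 64 of 86 genes higher and 2 lower (66 and 2 adjusted over the list alone). The list's median was 0.83, with a camera adjusted p of 6.49e-20 (adjusted p = 0.0547 with an estimated correlation). Its main chaperone gene, hspa5.L, rose by 2.52 ± 0.18 to 759.7 ± 98.2 CPM from 133.5 ± 28.3 CPM, and manf.L, manf.S and dnajb9.S rose by 2.65 ± 0.16, 2.32 ± 0.12 and 2.18 ± 0.15. Of 63 proteasome genes, 57 rose and 1 fell (58 and 1 adjusted over the list alone). Its median was 0.84, and the camera adjusted p was 1.22e-15 (adjusted p = 0.260 with an estimated correlation). Among them were psmd4.L (1.28 ± 0.14), psmb4.S (1.20 ± 0.12), psmd8.S (1.12 ± 0.13) and psmd14.S (1.0 ± 0.13).

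The list of the amino acid response had 28 of 66 genes higher and 15 lower (29 and 15 adjusted over the list alone). Here the median was 0.28, with a camera adjusted p of 0.0092 (adjusted p = 0.565 with an estimated correlation). Its genes with the smallest p were psat1.L (4.98 ± 0.28), psph.L (2.42 ± 0.20) and shmt2.L (1.65 ± 0.12), enzymes of serine and glycine synthesis, and the stress regulator gene nupr1.L, which fell by 1.95. Of 45 genes of autophagy and FoxO targets, 28 fell and 4 rose (31 and 4 adjusted over the list alone). For the list as a whole the median was -0.78 and the camera adjusted p 5.18e-08 (adjusted p = 0.104 with an estimated correlation). fbxo32.S, a ubiquitin ligase subunit of muscle wasting, had -4.32 ± 0.32, tp53inp1.S -2.36 ± 0.23, txnip.L -2.29 ± 0.19 and sesn1.L -2.03 ± 0.16. The list of gluconeogenesis and the fasting response had 13 of 38 genes lower and 3 higher (12 and 2 adjusted over the list alone). The list's median was -0.32, with a camera adjusted p of 0.0167 (adjusted p = 0.260 with an estimated correlation). Among them were the gluconeogenic pck1.S (-1.98 ± 0.21) and pck1.L (-1.51 ± 0.17), klf15.S (-1.99 ± 0.20) and the insulin receptor substrate gene irs2.L (-1.32 ± 0.13). Lysosome genes had 13 of 41 lower and 3 higher (12 and 2 adjusted over the list alone). Its median was -0.37, and the camera adjusted p was 0.0206 (adjusted p = 0.528 with an estimated correlation). Among them were grn.L (-1.68 ± 0.16), lrp2.L (-1.53 ± 0.22), glb1.L (-1.22 ± 0.18) and gusb.S (-1.15 ± 0.17).

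Defence and leukocyte genes were lower in fed tadpoles. Of 45 genes of intestinal defence and oxidant enzymes, 32 fell and 0 rose (34 and 0 adjusted over the list alone). Here the median was -1.73 or -1.69 with genes near 0 counts at their bound, with a camera adjusted p of 1.93e-10 (adjusted p = 0.389 with an estimated correlation). The transcription factor genes irf1.L and irf1.S had -2.50 ± 0.19 and -2.41 ± 0.14 and the cytokine signalling inhibitor gene socs3.S -3.18 ± 0.31; nos2.L, a nitric oxide synthase, had 1 count over the fed libraries and was 134-fold higher in unfed libraries (interval 23.7 to 5320). Among 46 leukocyte markers, 39 fell and 0 rose (42 and 0 adjusted over the list alone). For the list as a whole the median was -0.89 and the camera adjusted p 1.13e-08 (adjusted p = 0.287 with an estimated correlation). Examples are tyrobp.S (-2.05 ± 0.27), the eosinophil peroxidase gene epx.L (-1.76 ± 0.25), plek.L (-1.70 ± 0.26) and the myeloperoxidase gene mpo.L (-1.02 ± 0.16). Both lists stood apart by experiment in unfed tadpoles. Defence genes took 0.0846% and 0.127% of the gene counts in the unfed libraries of experiment 1 and 0.146%, 0.175% and 0.222% in those of experiment 2, against 0.0533% to 0.0654% in fed libraries. Leukocyte genes took 0.0718% and 0.0885% in experiment 1 and 0.127% to 0.159% in experiment 2, against 0.0518% to 0.0663% in fed libraries. Of 30 interferon response genes, 14 fell and 2 rose (14 and 2 adjusted over the list alone). The list's median was -0.48, with a camera adjusted p of 0.00122 (adjusted p = 0.389 with an estimated correlation). Among them were irf9.L (-2.03 ± 0.14), the RNA sensor gene dhx58.L (-1.94 ± 0.19) and irf7.L (-1.12 ± 0.15). The other copy, dhx58.S, did not pass in edgeR (-0.12, adjusted p 0.571).

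**Figure D3:**
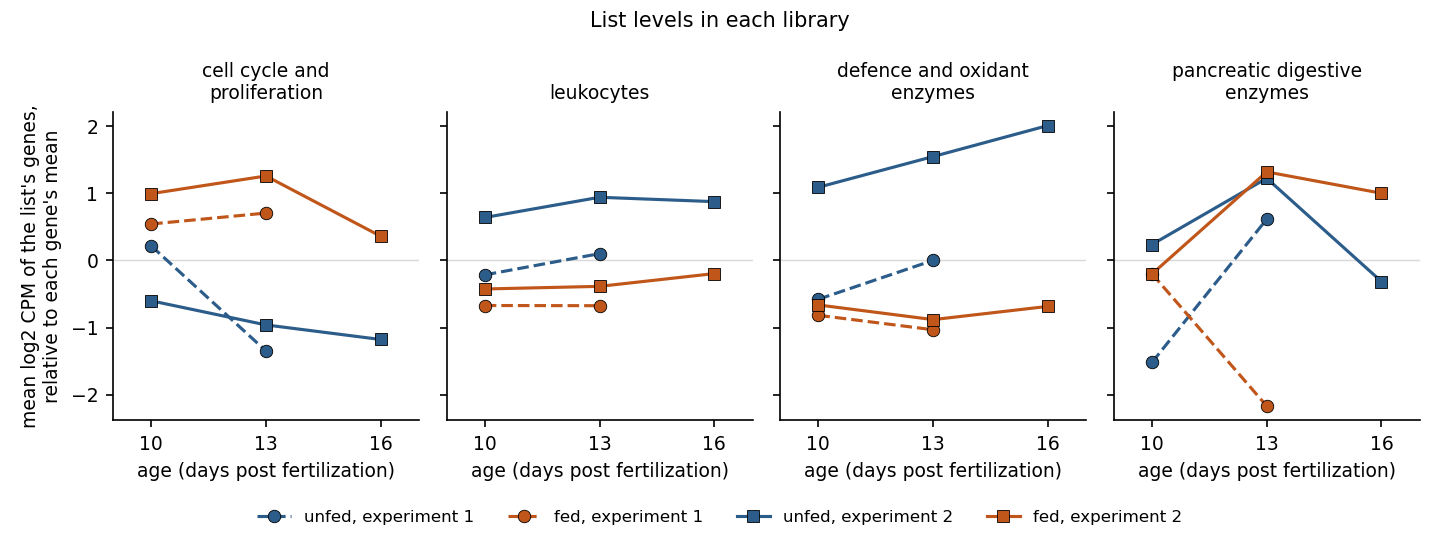
Mean log2 CPM of the genes of 4 lists relative to each gene's mean over the libraries, by age in dpf; each point is 1 library, coloured by feeding, and lines join the libraries of 1 feeding state and experiment. Defence and leukocyte genes lie lower in fed libraries of both experiments, but the defence median differed by only -0.02 in the 10 dpf pair of experiment 1. Pancreatic enzymes have fed minus unfed medians from -2.90 to 1.30 among the 5 pairs.

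Among the marker lists of other cell types of the gut, enteric neurons and glia had 15 of 38 genes lower and 2 higher (14 and 2 adjusted over the list alone). Its median was -0.47, and the camera adjusted p was 0.0421 (adjusted p = 0.438 with an estimated correlation). Among them were erbb3.L (-1.50 ± 0.17), erbb3.S (-1.28 ± 0.18), nos1.L (-0.85 ± 0.16) and the neuropeptide gene vip.S (-0.81 ± 0.15). The enteric list's call was lost without any 1 of 6 libraries, with camera adjusted p of 0.0682 (without fed 10 dpf replicate 1), 0.0548 (fed 13 dpf replicate 1), 0.136 (unfed 10 dpf replicate 1), 0.055 (fed 10 dpf replicate 2), 0.0688 (fed 16 dpf replicate 2) and 0.0571 (unfed 16 dpf replicate 2). Intestinal stem and progenitor cells (40 genes) had 5 genes higher and 17 lower, with a median of -0.55 and a camera adjusted p of 0.0991; the cell division gene cdca7.L rose by 2.65 ± 0.21 and cdca7.S by 2.30 ± 0.26, while cd44.L and the Notch ligand gene dll4.L had -0.98 ± 0.14 and -1.25 ± 0.19. Enteroendocrine cells (36 genes) had 12 higher and 3 lower, a median of 0.23 and a camera adjusted p of 0.0991, and the hormone genes pyy.S (1.31 ± 0.14), gip.S (1.03 ± 0.16) and gcg.L (1.14 ± 0.20) and the granule gene chga.L (0.83 ± 0.15) rose. The enteroendocrine list passed without fed 13 dpf replicate 1 (camera adjusted p 0.0481). The goblet list (20 genes; 5 higher, 4 lower; camera adjusted p 0.772) had a median of 0.22 and a mean of -0.004; tff3.1.S (3.54 ± 0.50) and agr2.L (1.18 ± 0.23) rose, and clca3p.S (-1.65 ± 0.28) and clca1.3.L (-1.16 ± 0.21) fell. For the enterocyte brush border (50 genes; 8 higher, 3 lower; 3 and 3 adjusted over the list alone) the median was 0.19 and the camera adjusted p 0.519. There, the glucose transporter gene slc2a2.S rose by 1.0 ± 0.21 and anpep.S (-2.20 ± 0.41), alpi.1.L (-1.28 ± 0.29) and slc6a19.S (-1.11 ± 0.24) fell. Lipid absorption and lipoproteins (38 genes; 16 higher, 5 lower) had a median of 0.69 and a camera adjusted p of 0.0815. Of its genes with the smallest p, sar1b.L, needed for chylomicron export, rose by 1.56 ± 0.20, while the triglyceride synthesis genes dgat2.S (-2.59 ± 0.22) and lpin1.S (-2.06 ± 0.25) and the cholesterol exporter gene abca1.S (-1.36 ± 0.20) fell. Without any 1 of 4 libraries the lipid absorption list passed, with camera adjusted p of 0.00889 (without fed 10 dpf replicate 1), 0.0225 (unfed 10 dpf replicate 1), 0.0364 (unfed 13 dpf replicate 1) and 0.0446 (unfed 10 dpf replicate 2), and without the replicate block (0.0409).

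For the smooth muscle and mesenchyme list (54 genes; 9 higher, 11 lower; 8 and 10 adjusted over the list alone) the median was -0.09 and the camera adjusted p 0.772; cnn2.L (1.43 ± 0.16) and cnn2.S (1.11 ± 0.15) rose and the fibronectin gene fn1.S (-2.05 ± 0.16) and vim.S (-1.08 ± 0.15) fell. Blood vessels and red cells (33 genes; 10 higher, 5 lower) had a median of 0.63 and a camera adjusted p of 0.0984, and the haem synthesis genes slc25a37.L (2.57 ± 0.29), slc25a37.S (1.83 ± 0.21), fech.L (1.45 ± 0.23) and urod.L (0.89 ± 0.13) rose. This list passed without fed 13 dpf replicate 1 (camera adjusted p 0.037), unfed 10 dpf replicate 1 (0.0378) or fed 10 dpf replicate 2 (0.0251). The liver list (35 genes; 4 higher, 7 lower; median -0.41; camera adjusted p 0.320) held ttr.S (1.94 ± 0.31) and apoc2.L (1.21 ± 0.22), which rose, and the coagulation factor gene f5.L (-1.21 ± 0.16), which fell with arg1.L. The list of pancreatic digestive enzymes (19 genes) also holds the progenitor factor gene ptf1a.L. Of these genes 0 passed by edgeR (median 0.01, camera adjusted p 0.982), with ctrb2.L at 1.92 ± 0.81 (adjusted p 0.0692) and cel.2.L at -1.50 ± 0.63 (adjusted p 0.0895). The list took 0.0167% of the gene counts in the fed 13 dpf and 0.0297% in the unfed 10 dpf library of experiment 1, and up to 0.294% elsewhere. ctrb2.L passed without fed 13 dpf replicate 1 (adjusted p 0.00595) or unfed 13 dpf replicate 1 (0.0264). Islet hormones (25 genes; 2 higher, 1 lower) had a median of 0.07 and a camera adjusted p of 0.697, with isl1.S at -0.86 ± 0.18. The stomach list (10 genes; 2 higher, 1 lower; 2 and 0 adjusted over the list alone) had a median of 0.08 and a camera adjusted p of 0.727, with gkn1.S (3.10 ± 0.61) and ctse.L (1.01 ± 0.21) higher and the proton pump gene atp4a.S lower (-0.78 ± 0.30, adjusted p 0.0448). The atp4a.S call was lost (adjusted p up to 0.15) without any 1 of the libraries other than unfed 13 dpf replicate 2 and the 16 dpf pair, and without the replicate block (0.145).

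In the lung and kidney list (10 genes; 2 higher, 5 lower; 2 and 6 adjusted over the list alone) the median was -0.89 and the camera adjusted p 0.255; napsa.L (-1.36 ± 0.21), wt1.S (-1.25 ± 0.27) and wt1.L (-0.94 ± 0.20) fell and slc22a6.S rose by 0.90 ± 0.19. Skeletal muscle (13 genes; 3 higher, 2 lower) had a median of -0.25 and a mean of -0.15, while its camera test pointed up (adjusted p 0.920); tnnt1.S (2.21 ± 0.29) and myh6.S (1.13 ± 0.36) rose and ryr1.L (-1.35 ± 0.35) and tnnt3.L (-1.14 ± 0.28) fell. The myh6.S call was lost without fed 10 dpf replicate 2 (adjusted p 0.0605), fed 16 dpf replicate 2 (0.0568), unfed 16 dpf replicate 2 (0.0546) or the replicate block (0.101). Thyroid hormone response genes (28; 5 higher, 12 lower; 5 and 13 adjusted over the list alone) had a median of -0.40 and a camera adjusted p of 0.286, with the coactivator gene ncoa3.S lower (-1.68 ± 0.14) and prmt1.S (1.84 ± 0.20), rcc1.L (1.75 ± 0.22) and prmt1.L (1.69 ± 0.16) higher. The circadian clock list (28 genes; 5 higher, 5 lower) had a median of 0.04 and a camera adjusted p of 0.920; usp2.L rose by 2.65 ± 0.15 and cry2.L (-1.80 ± 0.23), cry2.S (-1.42 ± 0.19) and per3.S (-1.34 ± 0.15) fell.

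**Figure D4:**
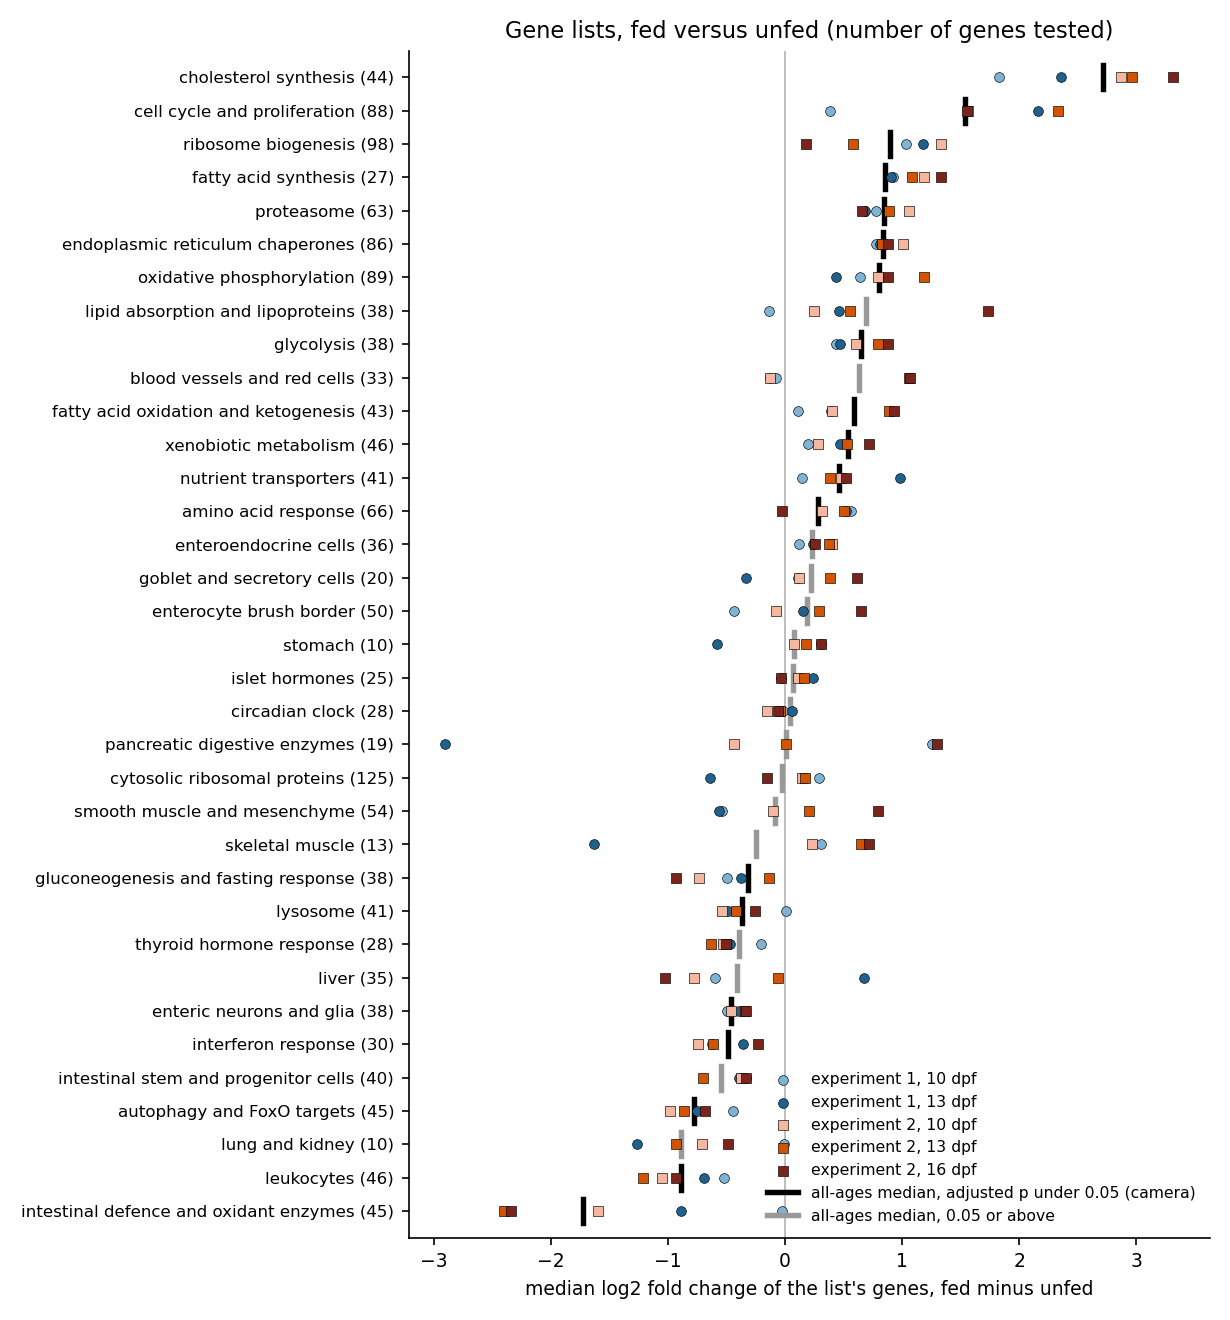
Median log2 fold change (fed minus unfed) of the 35 gene lists, with the number of genes tested; bars are the all-ages medians, black where the camera adjusted p passed, and points are the medians of the 5 pairs of libraries. Cholesterol synthesis has the highest median (2.72) and intestinal defence and oxidant enzymes the lowest (-1.73).

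Over all genes, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 11542 of 23081 genes (50%), 5700 higher and 5842 lower in fed tadpoles, of which 2041 and 2553 changed at least 2-fold. At an unadjusted p under 0.05 there were 13052 genes, against 1154 that chance gives. The camera test called 19 of 35 lists, 12 higher and 7 lower; 0 passed with an estimated correlation (lowest adjusted p = 0.0547), and fry called 23. Of the called genes, 10101 had the same sign in all 5 pairs. The same libraries gave the calls, so this count is no separate evidence for them. Of all genes tested, called or not, 50% had the same sign in all 5 pairs, against 6.25% by chance. Without the replicate block for the experiment 9758 genes passed and with a block for each pair 11264. Experiment 1 alone (4 libraries) called 3686 genes, and with library size alone as the scaling, which moved the median fold change of all genes from -0.04 to -0.21 (a shift of -0.17), the split was 4001 higher and 7278 lower. Under that scaling 0 of the 19 called lists and 0 of the 148 named genes past the threshold changed sign, and the medians of the pancreatic, islet, stomach and clock lists, which did not pass, turned negative. Among the called lists the median moved by more than 1.5 times in the amino acid response (0.12), nutrient transporters (0.29) and gluconeogenesis and the fasting response (-0.49).

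At 10 dpf, with 2 fed and 2 unfed libraries, fads1.L (7.13 ± 0.34, adjusted p 1.91e-06) and slc34a2.S (6.38 ± 0.68, adjusted p 0.00139) again had the highest fold changes. The sterol genes msmo1.L (5.18 ± 0.46), msmo1.S (5.06 ± 0.45), sqle.L (5.06 ± 0.34) and sqle.S (4.68 ± 0.34) followed, with psat1.L (4.70 ± 0.45) of serine synthesis and inhbc.1.S, described as an inhibin chain (5.15 ± 0.72). Lowest were crebrf.S (-4.75 ± 0.44, adjusted p 0.000151) and its copy crebrf.L (-3.32 ± 0.46), cxcl8.S (-3.93 ± 0.87, adjusted p 0.029), the fatty acid receptor gene cd36.S (-3.81 ± 0.42), faah.1.S (-3.41 ± 0.37), noxo1.S (-3.35 ± 0.55), tnfsf10.L (-3.26 ± 0.25) and ypel1.L (-3.24 ± 0.27). Cholesterol synthesis had 36 of 44 genes higher and 0 lower (38 and 0 adjusted over the list alone). Here the median was 2.37, with a camera adjusted p of 4.28e-48 (adjusted p = 0.235 with an estimated correlation). Ribosome biogenesis had 72 of 98 genes higher and 0 lower (78 and 1 adjusted over the list alone). For the list as a whole the median was 1.22 and the camera adjusted p 1.12e-26 (adjusted p = 0.445 with an estimated correlation). The cell cycle list had 31 of 88 higher and 0 lower (35 and 0 adjusted over the list alone). The list's median was 0.84, with a camera adjusted p of 5.01e-13 (adjusted p = 0.506 with an estimated correlation). Defence genes had 13 of 47 lower and 0 higher (13 and 0 adjusted over the list alone). Its median was -1.28 or -0.86 with genes near 0 counts at their bound, and the camera adjusted p was 3.53e-06 (adjusted p = 0.506 with an estimated correlation). In the 10 dpf pair of experiment 1 the defence median was -0.02 and in that of experiment 2 it was -1.60 (45 genes). Liver genes had 8 of 38 lower and 2 higher, the same adjusted over the list alone (median -0.79; camera adjusted p 0.00653; adjusted p = 0.482 with an estimated correlation).

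Of 23787 genes tested at 10 dpf, edgeR called 4831 (20.3%), 2652 higher and 2179 lower, of which 1751 and 1615 changed at least 2-fold; with library size alone the split was 1476 higher and 2340 lower. Of the 35 lists 11 passed higher and 8 lower with camera, 0 passed with an estimated correlation (lowest adjusted p = 0.235) and fry called 9; test and median differed in sign in 3 lists and mean and median in 4. Without the replicate block 1781 genes passed, and with the DESeq2 Wald test 3148. The age from the stage field also gave fewer genes, but it leaves a single unfed library at 10 dpf. Leaving out a library moved the count to 821 (unfed 10 dpf replicate 2), 923 (fed 10 dpf replicate 2), 2436 (unfed 10 dpf replicate 1) or 2766 (fed 10 dpf replicate 1), where the lone library of an arm is assumed to vary like the other groups, and inhbc.1.S, cxcl8.S and noxo1.S each lost their call in at least 1 such setting.

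At 13 dpf, with 2 libraries of each feeding state, slc34a2.S (7.29 ± 0.73, adjusted p 0.000618), fads1.L (6.94 ± 0.35, adjusted p 2.85e-06) and fads2.S (6.65 ± 1.39, adjusted p 0.0266) had the highest fold changes. They were followed by the sterol genes msmo1.S (6.33 ± 0.48), msmo1.L (6.19 ± 0.49), sqle.L (6.06 ± 0.37), cyp51a1.S (5.92 ± 0.51) and sqle.S (5.69 ± 0.36). steap4.2.L, a metalloreductase, had 0 counts in both fed libraries and was at least 32.6-fold lower there, against a floor of 3 counts per library (adjusted p 8.26e-05). fgf19.L, a hormone of the bile acid circuit, had 3 counts in the fed libraries and was 46.7-fold higher in the unfed ones (interval 15.7 to 229; adjusted p 0.0326). The other lowest genes were noxo1.S (-5.46 ± 0.54), mmp8.L (-5.36 ± 1.41, adjusted p 0.0483), cxcl8.S (-5.18 ± 0.999), arg1.L (-4.90 ± 0.75), clca1.2.L (-4.64 ± 1.19, adjusted p 0.0458) and acod1.L (-3.98 ± 1.06, adjusted p 0.0374). The size of some rests on single libraries: acod1.L had -0.96 without fed 13 dpf replicate 2, and mmp8.L had -2.89 without unfed 13 dpf replicate 2. The cell cycle list had 79 of 88 genes higher and 0 lower (85 and 0 adjusted over the list alone). Here the median was 2.26, with a camera adjusted p of 9.41e-39 (adjusted p = 0.413 with an estimated correlation). Cholesterol synthesis had 38 of 44 higher and 1 lower (41 and 1 adjusted over the list alone). For the list as a whole the median was 2.75 and the camera adjusted p 2.44e-51 (adjusted p = 0.279 with an estimated correlation). Defence genes had 25 of 47 lower and 0 higher (26 and 0 adjusted over the list alone). The list's median was -2.21 or -1.60 with genes near 0 counts at their bound, with a camera adjusted p of 2.15e-11 (adjusted p = 0.413 with an estimated correlation). Leukocyte genes had 21 of 48 lower and 0 higher (28 and 0 adjusted over the list alone). Its median was -0.95, and the camera adjusted p was 2.68e-08 (adjusted p = 0.413 with an estimated correlation).

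Of 23787 genes tested at 13 dpf, edgeR called 7351 (30.9%), 3943 higher and 3408 lower, of which 2527 and 2455 changed at least 2-fold; with library size alone the split was 2516 higher and 3619 lower. In this comparison 13 lists passed higher and 5 lower with camera, 0 passed with an estimated correlation (lowest adjusted p = 0.279) and fry called 9; mean and median differed in sign in 1 list. Without the replicate block 3661 genes passed, and with the DESeq2 Wald test 4825. The age from the stage field also gave fewer genes, but it leaves a single fed library at 13 dpf. Leaving out unfed 13 dpf replicate 2 gave 2715 genes and leaving out unfed 13 dpf replicate 1 gave 3281, and 8 of the 16 named genes lost their call in at least 1 setting (fads2.S, steap4.2.L, fgf19.L, mmp8.L, cxcl8.S, arg1.L, clca1.2.L and acod1.L).

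The change of the fed minus unfed difference from 10 to 13 dpf was tested as such. No single gene passed in edgeR (0 of 23787; lowest adjusted p 0.178; 1237 genes at an unadjusted p under 0.05, against 1189 by chance), while DESeq2 called 21 and limma-voom 0. As lists, the cell cycle genes had the largest rise of the difference, with a median change of 1.41 log2 units (adjusted p = 0.63 with an estimated correlation), and liver (0.61), blood vessels and red cells (0.53), brush border (0.52) and cholesterol synthesis (0.52) followed. Over the list alone, 5 cell cycle genes and 9 liver genes passed upward and 1 liver gene downward. Pancreatic digestive enzymes (-1.79), skeletal muscle (-1.29) and defence genes (-0.50) had changes below 0. The camera test called 14 lists, 8 higher and 6 lower, of which 0 passed with an estimated correlation (lowest adjusted p = 0.63) or with fry. Single libraries decided several of these values: the cell cycle median was 0.50 without unfed 10 dpf replicate 1, the pancreatic median was -0.54 without fed 13 dpf replicate 1 and -3.43 without fed 13 dpf replicate 2, and the skeletal muscle median was 0.12 without unfed 13 dpf replicate 1. The titles and the stage field of unfed 10 dpf replicate 1 and fed 13 dpf replicate 1 give different ages, and with the age from the stage field the cell cycle median was 0.34 and the pancreatic median 0.38 (camera adjusted p 0.000771 and 0.326). The median of cytosolic ribosomal proteins (-0.40) was 0.08 without fed 13 dpf replicate 1. When single libraries were left out, the medians of blood vessels and red cells, cholesterol synthesis, brush border and liver were as low as 0.01, 0.15, 0.27 and 0.37. Those of liver and cholesterol synthesis were 0.175 and 0.06 with the age from the stage field. The count of single genes was 32 without unfed 10 dpf replicate 2, 11 and 9 without fed 13 dpf replicates 1 and 2, 6 without fed 10 dpf replicate 2 and 4 without unfed 13 dpf replicate 1.

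Between 10 and 13 dpf in unfed tadpoles, edgeR called 3 genes of 23787 (2 higher and 1 lower; 1481 at an unadjusted p under 0.05; 41 by DESeq2 and 0 by limma-voom). The count was also 0 without the replicate block, with the age from the stage field, with summed transcripts and with library size alone. None of the 3 has a symbol that the naming rule allows, and they are described here after their values were seen. A transcript described as Niemann-Pick C1-like protein 1, the intestinal cholesterol importer, was lower at 13 dpf (-3.35 ± 0.40, adjusted p 0.0279), with 381 and 125 counts at 10 dpf and 31 and 16 counts at 13 dpf, against 563 to 1044 counts in the fed libraries of these ages. An uncharacterized locus was higher (2.27 ± 0.28, adjusted p 0.0279), with 34 and 40 counts at 10 dpf and 172 and 202 counts at 13 dpf. Another, LOC108704225 (5.10 ± 0.50, adjusted p 0.0279), had 8 counts at 10 dpf and 345 at 13 dpf in experiment 2 and 0 counts in experiment 1. The call count was 1 without unfed 13 dpf replicate 2 and 79 without unfed 10 dpf replicate 2, 2 without unfed 10 dpf replicate 1, 5 without either fed 10 dpf library, 8 without either fed 13 dpf library and 11 without unfed 13 dpf replicate 1, and simulated data gave 9 false calls. By camera, 6 lists were higher at 13 dpf and 10 lower, 0 with an estimated correlation (lowest adjusted p = 0.679) and 0 with fry. The cell cycle list had the lowest median (-1.24, adjusted p = 0.679 with an estimated correlation), with 0 genes higher and 21 lower adjusted over the list alone and 0 past the threshold over all genes. Pancreatic enzymes had the highest (1.69, adjusted p = 0.708 with an estimated correlation). The cell cycle median was -0.24 without unfed 10 dpf replicate 1 and -1.75 without unfed 10 dpf replicate 2, and the pancreatic median 1.05 and 2.39 without unfed 13 dpf replicates 1 and 2. With the age from the stage field they were 0.13 (camera adjusted p 0.939) and 0.95 (0.00784).

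In fed tadpoles, edgeR called 0 of 23787 genes between 10 and 13 dpf (444 at an unadjusted p under 0.05, against 1189 by chance; 2 by DESeq2 and 0 by limma-voom). By camera, cholesterol synthesis (median 0.22), the cell cycle (0.24), liver (0.33) and blood vessels and red cells (0.22) were higher at 13 dpf, and cytosolic ribosomal proteins (-0.15), oxidative phosphorylation (-0.10) and skeletal muscle (-0.54) were lower. Of these 7 lists 0 passed with an estimated correlation (adjusted p = 0.915) or with fry. The sign of 6 of these medians turned when single libraries were left out. Cholesterol synthesis ran from -0.02 (without fed 10 dpf replicate 1) to 0.56 (fed 10 dpf replicate 2) and skeletal muscle from -0.92 (fed 10 dpf replicate 1) to 0.01 (fed 13 dpf replicate 1). Without fed 13 dpf replicates 2 and 1 in turn, the medians were -0.10 and 0.45 (cell cycle), -0.29 and 0.52 (vessels and red cells), -0.68 and 0.34 (ribosomal proteins) and -0.53 and 0.26 (oxidative phosphorylation). Under the age from the stage field, fed 13 dpf replicate 2 is the only fed library at that age. The medians of ribosomal proteins (0.36), oxidative phosphorylation (0.315) and skeletal muscle (0.28) then lay above 0. Those of cholesterol synthesis (0.33), the cell cycle (0.42), vessels and red cells (0.49) and liver (0.08) did so as well. With the ages of the titles the liver median ran from 0.20 (without fed 10 dpf replicate 1) to 0.70 (fed 13 dpf replicate 2). The count of single genes was 4 without fed 13 dpf replicate 1 and 3 without fed 13 dpf replicate 2.

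Whether the feeding effect differed between the experiments was tested with the feeding by experiment term. edgeR called 0 of 23081 genes (lowest adjusted p 0.059; 1571 at an unadjusted p under 0.05, against 1154 by chance), DESeq2 called 111 and limma-voom 0. The edgeR count was 86 without fed 10 dpf replicate 2, 51 without unfed 10 dpf replicate 2, 4 without either 16 dpf library and 1 without fed 13 dpf replicate 1. Across genes the fed minus unfed log2 changes of the experiments correlated with r 0.81, and 82.3% had the same sign. Of the 3686 genes called in experiment 1 alone, 98.8% had the same sign in experiment 2, and of the 9500 called in experiment 2 alone, 95.6% had it in experiment 1. The cholesterol synthesis median lay between 1.83 and 3.32 in the 5 pairs and the leukocyte median between -1.22 and -0.52. Other lists varied more: the defence median was -0.02 and -0.89 in experiment 1 and -1.60, -2.40 and -2.34 in experiment 2, and the cell cycle median 0.38 and 2.16 in experiment 1 and 1.56, 2.33 and 1.56 in experiment 2 (in order of age).

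At 16 dpf, with 1 fed and 1 unfed library and no test, fads2.S (log2 ratio 7.47, interval 6.92 to 8.69), fads1.L (7.12), msmo1.L (6.94), sqle.L (6.57) and sqle.S (6.46) were again among the highest ratios. The highest was hbg2.L, a haemoglobin gene whose deposited description names the S copy (8.40, interval 7.76 to 10.33, 1834 against 6 counts). At 13 dpf hbg2.L did not pass in edgeR (4.39, adjusted p 0.192). Among the lowest, cxcl8.S had 3 counts in the fed and 1230 in the unfed library (log2 ratio -7.46, interval -10.33 to -6.50), and csf3.L, which encodes a myeloid growth factor, had 0 against 212 counts and was at least 45.8-fold lower. The metalloproteinase genes mmp1.S (-6.39), mmp8.L (-6.02) and mmp9.2.L (-6.02, interval -12.67 to -4.87, 1 fed count) and fosl1.L (-6.20, interval -12.85 to -5.05, 1 fed count) completed the lowest 6. Of these, mmp1.S (-3.65, adjusted p 0.135) and fosl1.L (-2.57, adjusted p 0.0661) did not pass in edgeR at 13 dpf. Among random lists matched on expression, the medians of cholesterol synthesis (3.32), lipid absorption and lipoproteins (1.73), the cell cycle (1.56), pancreatic digestive enzymes (1.30) and blood vessels and red cells (1.06) lay at the percentile 100. So did those of fatty acid synthesis (1.33), fatty acid oxidation and ketogenesis (0.93), glycolysis (0.88), oxidative phosphorylation (0.88), endoplasmic reticulum chaperones (0.88), smooth muscle and mesenchyme (0.80) and the proteasome (0.66). Those of defence genes (-2.34), liver (-1.02), leukocytes (-0.94), gluconeogenesis and the fasting response (-0.94), autophagy and FoxO targets (-0.68) and cytosolic ribosomal proteins (-0.15) lay at the percentile 0. Of 7314 genes called at 13 dpf and measured at 16 dpf, 6985 (95.5%) had the same sign at 16 dpf, against 79.1% of all genes, and the log2 changes of both ages correlated across 23081 genes with r 0.757.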

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

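In this part the list tests with an estimated correlation, fry, the age from the stage field or 1 library left out, and every test of the pancreatic, leukocyte and defence patterns, were chosen only after the result was seen. For 14 lists the fed minus unfed difference changed from 10 to 13 dpf by the camera test at the preset correlation, which is why they are given here. With an estimated correlation the adjusted p was 0.63 for each of them, and fry called 0. The changes rest on 8 libraries, and each median (log2) is followed by its lowest and highest value when 1 of these 8 was left out.

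Above 0 were the cell cycle (1.41; 0.50 without unfed 10 dpf replicate 1 to 1.96 without unfed 10 dpf replicate 2), liver (0.61; 0.37 without unfed 13 dpf replicate 1 to 0.79 without unfed 13 dpf replicate 2) and blood vessels and red cells (0.53; 0.01 without fed 13 dpf replicate 2 to 0.76 without fed 13 dpf replicate 1). The brush border followed (0.52; 0.27 without fed 10 dpf replicate 1 to 0.76 without unfed 13 dpf replicate 1), with cholesterol synthesis (0.52; 0.15 without unfed 10 dpf replicate 1 to 0.85 without fed 10 dpf replicate 2). Lipid absorption and lipoproteins had 0.43 (0.20 without fed 10 dpf replicate 1 to 0.73 without fed 10 dpf replicate 2). Fatty acid oxidation and ketogenesis had 0.39 (0.13 without unfed 13 dpf replicate 2 to 0.60 without unfed 13 dpf replicate 1), and nutrient transporters 0.32 (-0.06 without fed 13 dpf replicate 1 to 0.66 without fed 10 dpf replicate 2). In each of the 8 removals the medians of these lists stayed above 0, except that of nutrient transporters.

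Below 0 were pancreatic digestive enzymes (-1.79; -3.43 without fed 13 dpf replicate 2 to -0.54 without fed 13 dpf replicate 1) and skeletal muscle (-1.29; -2.06 without unfed 13 dpf replicate 2 to 0.12 without unfed 13 dpf replicate 1). Intestinal defence and oxidant enzymes had -0.50 (-1.32 without unfed 10 dpf replicate 2 to 0.07 without fed 13 dpf replicate 2), and cytosolic ribosomal proteins -0.40 (-0.95 without fed 13 dpf replicate 2 to 0.08 without fed 13 dpf replicate 1). Ribosome biogenesis had -0.26 (-0.61 without fed 13 dpf replicate 1 to 0.04 without fed 13 dpf replicate 2) and leukocytes -0.20 (-0.49 without unfed 10 dpf replicate 2 to -0.002 without unfed 13 dpf replicate 2).

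The titles and the stage field of unfed 10 dpf replicate 1 and fed 13 dpf replicate 1 give different ages. The headers of the count columns give the ages of the titles, but these changes depend on which is right. With the age from the stage field the camera test at the preset correlation still called the cell cycle (0.34), blood vessels and red cells (0.47), brush border (0.30), lipid absorption (0.26), fatty acid oxidation (0.35), ribosome biogenesis (-0.67) and defence (-0.80). It no longer called liver (0.17), cholesterol synthesis (0.06), nutrient transporters (0.10), leukocytes (-0.30), pancreatic enzymes (0.38), skeletal muscle (0.36) or cytosolic ribosomal proteins (0.04), of which the last 3 changed sign.

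The pancreatic enzymes differed 12.2-fold in mean level between libraries, with fed minus unfed medians from -2.90 to 1.30 among the 5 pairs, and since the lowest and the highest library (-2.24 and 1.37 log2) were both fed, feeding is not the whole cause of the spread. A candidate explanation is the amount of pancreas taken with the intestine: 89% of the variance of 18 enzymes lay on 1 component (random lists: median 59.5%, highest 85.5% of 1000). The insulin gene ins.S, with 1 to 22 counts per library, followed it (rho 0.891, adjusted p 0.00324; r 0.843 without the 2 farthest libraries, and 0.863 within the 6 libraries of experiment 2). The progenitor factor gene ptf1a.L did so less firmly (rho 0.842, r 0.802, or 0.511 without the 2 farthest), and gcg.L, which the gut also expresses, had rho -0.176. The islet hormone list (25 genes) did not move with the enzymes. Its fed minus unfed medians were -0.035 and 0.238 in experiment 1 and 0.108, 0.164 and -0.038 in experiment 2, in order of age. Those of the enzyme list were 1.253 and -2.903, and -0.439, 0.007 and 1.297. Changes in enzyme expression by the pancreas itself, with age or between the experiments, stay open, no sorting step removed such cells, and which of the enzymes the intestine makes was not tested.

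Leukocyte and defence genes were lower in fed tadpoles, with medians of -0.89 and -1.73. A larger share of epithelium in the fed intestine would lower all other cell types alike. The medians of the vessel and red cell, smooth muscle and neuron lists lay 1.52 (95% interval 0.86 to 1.89), 0.80 (0.67 to 0.99) and 0.42 (0.28 to 0.66) above the leukocyte median (intervals here resample genes, not libraries). In experiment 2, in order of age, smooth muscle (-0.11, 0.21 and 0.80) and neurons (-0.46, -0.34 and -0.33) lay above leukocytes in each pair. There the gaps argue against a larger share of epithelium as the whole cause, provided that feeding did not change these genes within their cells. That condition was not tested. In the pairs of experiment 1 a larger share of epithelium stays open, since smooth muscle (-0.54 and -0.57) and neurons (-0.49 and -0.40) lay near leukocytes there. The median of the enterocyte brush border list was -0.43 and 0.15 in experiment 1 and -0.075, 0.29 and 0.65 in experiment 2. The vessel and red cell median was -0.08 and -0.13 in experiment 1 and -0.13, 1.06 and 1.06 in experiment 2, in order of age. Fed and unfed libraries were compared within each experiment, so a difference in level between the experiments could not by itself lower a list in fed tadpoles. The fed minus unfed leukocyte median was -0.52 and -0.70 in the pairs of experiment 1, which hold the 2 libraries of conflicting age. It was -1.05, -1.22 and -0.94 in experiment 2, so its size may depend on the experiment as well, which was not tested. For the defence list part of the size may depend on the experiment: the median over 10 and 13 dpf was -0.53 in experiment 1 (33 of 45 genes lower; -0.02 in the 10 dpf and -0.89 in the 13 dpf pair) and -1.92 in experiment 2 (43 of 45), a difference of 1.39 (0.90 to 2.01), while the feeding by experiment term called 0 single genes in edgeR (1571 at an unadjusted p under 0.05; 111 by DESeq2). Fewer leukocytes in fed tadpoles, and lower expression in the same number of cells, both stay open as hypotheses, and the libraries hold no cell counts to part them.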

How the results depend on the processing

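Each single age rests on 4 libraries. When 1 is left out, the lone library of its arm is assumed to vary like the other groups. At the depths reached here, simulated 2-fold changes were recovered for 77.6% of the changed genes over all ages. At 10 and 13 dpf the shares were 11.9% and 10.4%. All these genes had a mean of at least 5 CPM. The tests with all transcripts, summed transcripts, library size alone, or without the 2 libraries of conflicting age were chosen only after the result was seen, as were the list tests with an estimated correlation or fry outside the all-ages comparison and the alternatives for genes named at a single age. Over all ages each alternative listed with the methods gave a gene count; the pair block, single experiments and 10 and 13 dpf alone were tried there only. The difference between experiments was not tried without the replicate block or with the age from the stage field, and the lists were not tried with the DESeq2 Wald test or limma-voom, nor over all ages with that age. Where no reason is given, the cause was not tested.

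Over all ages (11542 genes) the count was 3686 in experiment 1 alone, which has 4 libraries, and 23860 with all transcripts, where 47081 were tested. The other alternatives gave 8975 (summed .L and .S copies) to 11618 (limma-voom), and leaving out 1 library gave 9174 to 11244, with at least 78.9% of the genes kept.

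At 10 dpf (4831) the count was 3148 with the DESeq2 Wald test, 1781 without the replicate block, 2860 with the age from the stage field and 10420 with all transcripts. Leaving out 1 library gave 821 (unfed 10 dpf replicate 2) to 6827 (fed 13 dpf replicate 1), with 923, 2436 and 2766 without fed 10 dpf replicate 2, unfed 10 dpf replicate 1 and fed 10 dpf replicate 1. At 13 dpf (7351) the same 4 alternatives gave 4825, 3661, 3295 and 15520, and leaving out 1 library gave 2715 (unfed 13 dpf replicate 2) to 7372 (unfed 16 dpf replicate 2), with 3281 without unfed 13 dpf replicate 1. With all transcripts more entries were tested, and a removal at the same age leaves 1 library in an arm. The age from the stage field also leaves 1 library, in the unfed arm at 10 dpf and in the fed arm at 13 dpf.

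The change of the difference from 10 to 13 dpf (0 genes) had 2 without the low-count filter and 21 with DESeq2, and 0 to 32 with 1 library left out (32 without unfed 10 dpf replicate 2, 11 and 9 without fed 13 dpf replicates 1 and 2, 6 without fed 10 dpf replicate 2, 4 without unfed 13 dpf replicate 1). In unfed tadpoles, 13 against 10 dpf (3 genes) had 22 without the filter, 41 with DESeq2, and 0 with limma-voom, without the replicate block, with the age from the stage field, with summed transcripts or with library size alone. With 1 library left out it had 1 (unfed 13 dpf replicate 2) to 79 (unfed 10 dpf replicate 2), 2 without unfed 10 dpf replicate 1, 5 without either fed 10 dpf library, 8 without either fed 13 dpf library and 11 without unfed 13 dpf replicate 1. In fed tadpoles (0 genes) DESeq2 and the age from the stage field gave 2 each, and leaving out 1 library gave 0 to 4 (4 and 3 without fed 13 dpf replicates 1 and 2). The difference between experiments (0 genes) had 2 with DESeq2 size factors, 15 without the filter, 111 with DESeq2, 3 with all transcripts and 0 to 86 with 1 library left out (86 and 51 without fed and unfed 10 dpf replicate 2, 4 without either 16 dpf library, 1 without fed 13 dpf replicate 1).

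With an estimated correlation the number of lists past the threshold was 0 in place of 19 over all ages, 19 and 18 at 10 and 13 dpf, 14 for the change of the difference, and 16 and 7 between ages in unfed and fed tadpoles. With fry it was 23, 9, 9, 0, 0 and 0. Leaving out 1 library gave 17 to 20 lists over all ages. Of 35 lists there, 19 lost their call and 6 gained one in at least 1 of 14 settings, and 0 reversed. The share of genes with the same sign at 16 as at 13 dpf was 95.5%, 98.4% at an adjusted p under 0.01 and 95.4% with DESeq2 size factors. Of 152 genes named over all ages, 148 of which passed, 146 stayed on the same side of the threshold in each of 14 settings that gave a value (1 gene had none in 1 setting), 4 lost a call and 2 gained one. Of 16 genes at 10 dpf and 16 at 13 dpf, all past the threshold, 13 and 8 kept their call, and 0 reversed.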

Other observations

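In this part the gene families and the comparison of .L and .S copies were tests chosen only after the result was seen, as was the comparison with library size alone. Of 91 mitochondrial ribosomal protein genes, 78 rose and 1 fell in fed tadpoles (median 0.92; mrps11.L 1.80 ± 0.17, mrpl12.L 1.78 ± 0.18; camera adjusted p 5.9e-22, or adjusted p = 0.239 with an estimated correlation). Subunits of the chaperonin TCP1 (12 of 15 higher, 0 lower; median 0.71; cct2.L 1.49 ± 0.17, tcp1.S 1.37 ± 0.15) and vesicle coats (17 of 29 higher, 4 lower; median 0.52; sec24d.S 1.27 ± 0.14, sec23a.S 1.19 ± 0.13) rose with them. Smaller shares rose among aminoacyl-tRNA synthetases (14 of 29 higher, 5 lower; median 0.32; nars1.L 1.37 ± 0.15), mitochondrial carriers (20 of 53 higher, 8 lower; median 0.28) and translation initiation factors (30 of 75 higher, 8 lower; median 0.20). The helicase genes eif4a1.S and eif4a1.L rose by 2.03 ± 0.15 and 1.62 ± 0.16. Matrix metalloproteinases (1 of 19 higher, 12 lower; median -1.68; mmp9.1.S -2.06 ± 0.26, mmp14.L -1.15 ± 0.16), Krüppel-like factors (2 of 27 higher, 12 lower; median -0.47; klf15.L -3.15 ± 0.43) and integrins (0 of 29 higher, 15 lower; median -0.42; itgb4.S -1.17 ± 0.17) fell. For these 9 families the camera adjusted p was at most 0.0136, and the adjusted p was at least 0.239 with an estimated correlation. Keratins, claudins, histones, ubiquitin-specific peptidases and FoxO factors did not pass (camera adjusted p 0.809, 0.196, 0.18, 0.819 and 0.666). With library size alone the 9 medians kept their sign. They were 0.02 for initiation factors, 0.10 for mitochondrial carriers, 0.14 for aminoacyl-tRNA synthetases and 0.33 for vesicle coats. Those of keratins (0.17) and ubiquitin-specific peptidases (0.004) turned to -0.01 and -0.17.

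The .L and .S copies of a gene could be compared in 3520 pairs with a mean of at least 5 CPM for each copy, and this ratio does not depend on the scaling of the libraries. Both copies changed in the same direction in 1367 pairs and in opposite directions in 45, 1 copy alone passed in 1132 and neither in 976, and the log2 changes of the copies correlated with r 0.796. The feeding effect differed between the copies in 1121 pairs (31.8%). The difference with the smallest p was in dgat2, which makes triglycerides: dgat2.L had 36.1 CPM in fed and 23.4 CPM in unfed libraries, and dgat2.S 17.5 and 109 CPM (difference 3.27 log2 units, adjusted p 8.99e-06). For the fatty acid receptor gene cd36, with a larger difference, the copy cd36.L had 186 CPM in fed and 118 CPM in unfed libraries, and cd36.S had 13.4 and 70.3 CPM (difference 3.50, adjusted p 6.19e-05). The receptor gene ldlr rose in its copy ldlr.S (27.1 against 7.39 CPM), while ldlr.L did not pass (16.8 against 14.1 CPM, adjusted p 0.264; difference -1.64, adjusted p 6.19e-05).

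For the 11542 genes past the threshold over all ages, of 100 splits into 5 and 5 drawn from 126, 1 called as many, the real one, and the highest other called 1 gene. Each other split leaves the feeding effect in its residual spread, and the 12 others drawn that parted all 5 pairs (0 genes at most) are too few for a share under 0.05. Scaling by TMM is not the whole cause, since 9842 of the genes (85.3%) were called in the same direction with library size alone. Fold change fell with transcript length (rho -0.264; median 0.28 among the shortest and -0.32 among the longest transcripts), but once a length trend was taken out of each library 9375 of the genes (81.2%) were called in the same direction and 19 of the 19 lists still passed camera at the preset correlation (0 had passed with an estimated one, which was not run again), with oxidative phosphorylation at 0.52 in place of 0.80, while cytosolic ribosomal proteins, which had not passed (-0.02), did so lower in fed tadpoles (-0.38, camera adjusted p 1.96e-05). Of the genes called, 10101 had the same sign in all 5 pairs, but the same libraries gave the calls. A broad response to feeding stays a hypothesis.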
